A study of Homo sapiens with 6 samples.

How the data were processed

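The samples were 6 RNA-seq libraries of PANC-1 cells, 3 with a null control virus and 3 with SHMT2 knockdown lentivirus, grouped by their sample titles. Per the labels' protocols, total RNA was isolated with TRIzol and libraries were made with the NEBNext Ultra II RNA kit. The aligner, counting tool, genome build, annotation release and strand setting are not given in the sources used here. The authors deposited whole-number read counts per gene, per the file headers, for 20036 Ensembl genes. The deposited table also holds FPKM values, and the table's own counts, gene lengths and column totals give those FPKM values back, so they carry no further normalization. Of 19852 identifiers found in GENCODE 29, 79.0% had a start or end at the same GRCh38 position, and coordinates are printed as the table gives them. Without a stated strand setting, it is unknown whether reads of genes that overlap on opposite strands were told apart. The spans of 2767 genes of the table overlap another on the same strand, where no strand setting separates the reads. There were no counts in any library for 3573 genes, and 629 had no symbol.

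Library totals ran from 15405884 to 19075734 counts. Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which left 12292, scaled with TMM factors and fitted with the quasi-likelihood model without covariates. Genes with a Benjamini-Hochberg adjusted p below 0.05 are called higher or lower. Standard errors were derived from the log2 fold change and its F statistic. Levels are TMM-scaled CPM, each count divided by its library's scaled total. The biological coefficient of variation was 14.2%. For replicate checks, counts of each pair of libraries of a group were compared by chi-square.

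Before the data were examined, 45 gene lists of pathways, complexes and cell type markers were fixed, together with the design and the alternatives. Lists with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry. The result of 1 list is not reported here. Overlap of lists with called genes was tested with Fisher's exact test, 2-sided, so that both an excess and a shortfall of called members can pass. Genes named in the text follow a rule fixed at the same time. The rule takes SHMT2, the 8 largest rises and 8 largest falls among called genes with a symbol, a mean of at least 5 CPM and groups that do not overlap, and up to 4 called members per list by adjusted p. For lists with fewer than 2 called members it takes the 2 of highest mean. It adds the 4 called genes of smallest adjusted p, with ties ordered by unadjusted p, and SHMT1, MTHFD2, MTHFD1L, ALDH1L2 and SLC25A32 in any case. Genes named in the closing observations, and the first and last genes of windows, were chosen after their values were seen.

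The test was tried on simulated counts for 12176 genes past the filter, 199 of them changed, drawn from the means, spreads and library sizes of this comparison. It recovered 22% of genes changed 1.5-fold, 84% of those changed 2-fold and 100% of those changed 4-fold or 8-fold, and 14 of 166 calls were false (8.4%). A list of 25 genes shifted 1.5-fold was called, and 0 of 40 random lists were called by camera. Genes were drawn independently there, so this does not show how often camera calls lists of correlated genes falsely. Windows of neighbouring genes were tested on simulated values with 3 windows shifted by 0.8, of which 3 were found, with 0 others. Genes were independent there and no length or GC correction was made. Smaller shifts and correlated neighbours were not tried.

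Alternatives were other scaling factors, filters, tests (DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1)), thresholds, the replicate number as a block, protein-coding genes alone and each library left out in turn. Leaving out both libraries that stood apart was added after the data were seen. Log2 fold changes were corrected for gene length and GC content with a smooth trend (mgcv 1.9.3) over 12274 genes. The residuals were centred so that the median over all genes was kept. Length and GC content explained 9.5% of the variance of log2 fold change. With genes grouped by length, the median ran from -0.21 at a median length of 2320 bases to 0.22 at 12164 bases. Calls of genes and lists were made without this correction. No column of another sample was present.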

Results

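RNA was sequenced from PANC-1, an established human pancreatic cancer cell line, after delivery of a lentivirus that knocks down SHMT2 or of a null control virus. SHMT2 is the mitochondrial serine hydroxymethyltransferase, which converts serine to glycine and passes a one-carbon unit to folate. There were 3 libraries per group. The deposited read counts summed to 16256045, 15405884 and 16366452 in control replicates 1, 2 and 3, and to 19075734, 16748432 and 18316416 in knockdown replicates 1, 2 and 3. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The comparison asks which transcripts differ in PANC-1 cells that received the knockdown virus.

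SHMT2 itself (ENSG00000182199, chromosome 12, 57229573 to 57234935, plus strand) was lower in every knockdown library than in every control library. It had 2113, 2284 and 2417 counts in control replicates 1, 2 and 3 and 139, 56 and 101 counts in knockdown replicates 1, 2 and 3. Its normalised level fell from 146 ± 11.4 to 5.19 ± 1.74 CPM (mean ± SD, n = 3 per group), which left 3.55% of the control mean. The log2 fold change was -4.80 (SE 0.23, adjusted p = 1.04e-05, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment).

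Among the other folate enzymes, ALDH1L2, which oxidises formyl-tetrahydrofolate in mitochondria, rose from 1.97 ± 0.124 to 13.1 ± 2.65 CPM (SD, n = 3), a log2 fold change of 2.73 (SE 0.20). The folate carrier SLC19A1 fell by 1.47 on the log2 scale, from 41.4 ± 1.99 to 15.0 ± 1.42 CPM. MTHFD1L, the mitochondrial formate-producing synthetase, changed by -0.61 (SE 0.11) and its cytosolic counterpart MTHFD1 by -0.48 (SE 0.08). The cytosolic paralog SHMT1 changed by -0.27 (SE 0.09, adjusted p = 0.0322) and MTHFD2 by 0.39 (SE 0.13, adjusted p = 0.0414) in the edgeR test. Both of these calls were lost without control replicate 2 or 3 or knockdown replicate 1 or 3 (adjusted p from 0.0676 to 0.119), and MTHFD2 also without control replicate 1 (0.0945). SHMT1 also lost its call when scaled by library size alone (adjusted p = 0.145) and by limma on log2(FPKM + 1) (0.13), and MTHFD2 with upper-quartile factors (0.0619). SLC25A32, the mitochondrial folate carrier, lay at 0.819 ± 0.225 and 1.02 ± 0.16 CPM with no call (adjusted p = 0.398), and 69.7% of its exon bases are shared with another gene on the same strand, so its level is uncertain. Of 18 tested genes on the folate list, 4 rose and 6 fell (also 4 and 6 when adjusted over the list alone). The list was not called by camera (adjusted p = 0.58), and its median of -0.17 and mean of 0.02 differed in sign.

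**Figure D1:**
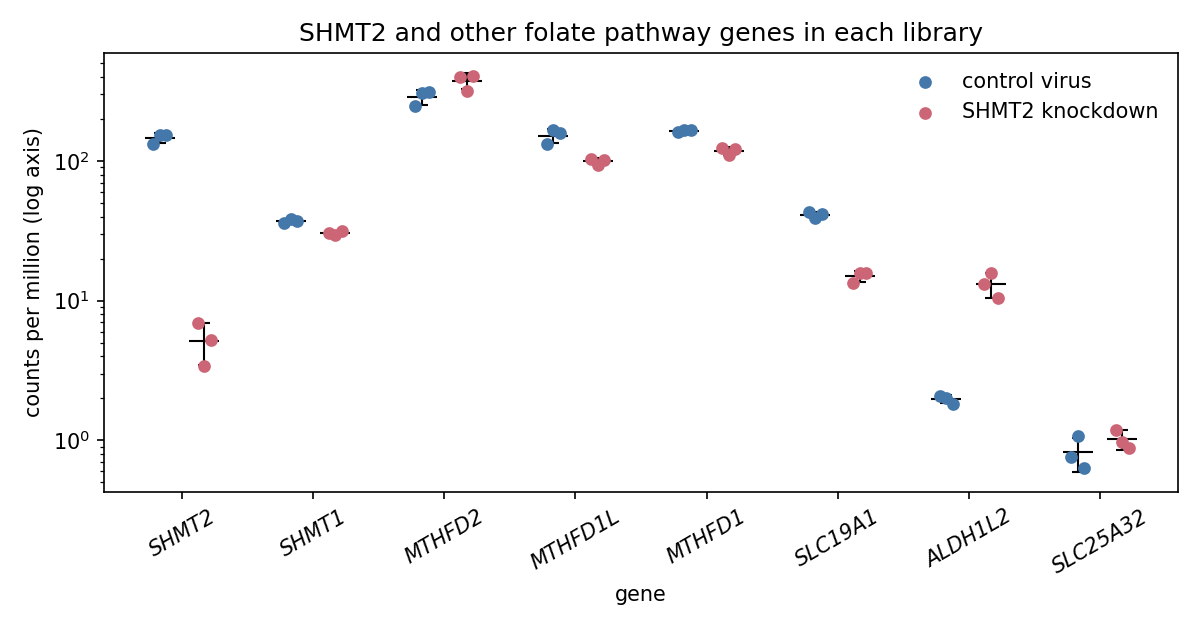
Normalised level in CPM (log axis) of SHMT2 and 7 other folate pathway genes in PANC-1 cells. Points are the 3 libraries per group, and horizontal bars with whiskers are the mean and SD. SHMT2 lies at 146 ± 11.4 CPM in control libraries and 5.19 ± 1.74 CPM in knockdown libraries.

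Of 18 tested serine and glycine genes, 7 fell and 3 rose (7 and 3 adjusted over the list alone). GLDC, a subunit of the glycine cleavage system, fell by 1.72 on the log2 scale (SE 0.19) to 3.03 ± 0.423 CPM (SD, n = 3). SFXN1, a mitochondrial serine transporter, changed by -0.58 and SFXN3 by -0.78. The list as a whole was not called by camera (adjusted p = 0.104), but was called with no filter on low counts (adjusted p = 0.0486).

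Across the transcriptome, 6372 of 12292 tested genes (51.8%) passed an adjusted p of 0.05 in the edgeR test, 3284 of them higher and 3088 lower in the knockdown libraries. At least 2-fold changes were seen in 1206 higher and 711 lower genes. The values of the groups did not overlap in 7553 genes (61.4%, where chance gives 10%). Among genes averaging at least 5 CPM, the rises of greatest size were KRT19, an epithelial keratin, at a log2 fold change of 8.79, DLC1 at 7.14, the laminin chain LAMA4 at 6.53 and the guanine deaminase GDA at 6.22. MEST (6.19), MME (6.02), MX2 (6.0) and SAMD9 (5.96) followed. KRT19 had 3, 4 and 0 counts in control replicates 1, 2 and 3 against 1523, 900 and 1518 in the knockdown replicates, so the size of its fold rests on few control counts. The same holds for DLC1 (0, 3 and 6 control counts), LAMA4 (5, 0 and 4) and MEST (1, 3 and 2). It also holds for MME (3, 3 and 4), MX2 (8, 3 and 1) and SAMD9 (7, 3 and 1), while GDA had 12, 18 and 10. The falls of greatest size were LRAT, which esterifies retinol, at -6.97 (346, 323 and 313 control counts against 4, 2 and 3), and the collagen COL22A1 at -5.09, followed after SHMT2 by FERMT1 (-4.21), TMCC3 (-4.19), LRRC15 (-4.04), ID2 (-3.66) and SORBS2 (-3.66). LRAT, COL5A2, APOL6 and SCARA3 had the smallest unadjusted p in edgeR, and their adjusted p of 2.54e-06 was shared by GDA, CCL2, TNFAIP2 and ABCG2, the last named after its value was seen. COL5A2 rose from 71.0 ± 3.43 to 578 ± 6.15 CPM, APOL6 rose from 2.70 ± 0.171 to 42.7 ± 1.5 CPM, and SCARA3 fell from 103 ± 3.60 to 11 ± 0.556 CPM (SD, n = 3).

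Libraries within a group were not equally close. Control replicate 1 and knockdown replicate 2 stood apart from the others of their group. A chi-square of counts per gene was 2.07 between control replicates 2 and 3 but 26 and 31.09 against replicate 1, and 2.46 between knockdown replicates 1 and 3 but 74.65 and 76.35 against replicate 2. All of these exceed sampling noise, so all 6 libraries were kept as separate samples. Knockdown replicate 2 had 10.42% of its counts in the 13 mitochondrially encoded genes, against 4.72% in both other knockdown libraries and 5.78% to 6.86% in the controls. Cytosolic ribosomal protein genes took 1.77% of its counts, against 3.22% and 3.40% in the other knockdown libraries and 3.06%, 4.24% and 4.41% in control replicates 1, 2 and 3.

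**Figure D2:**
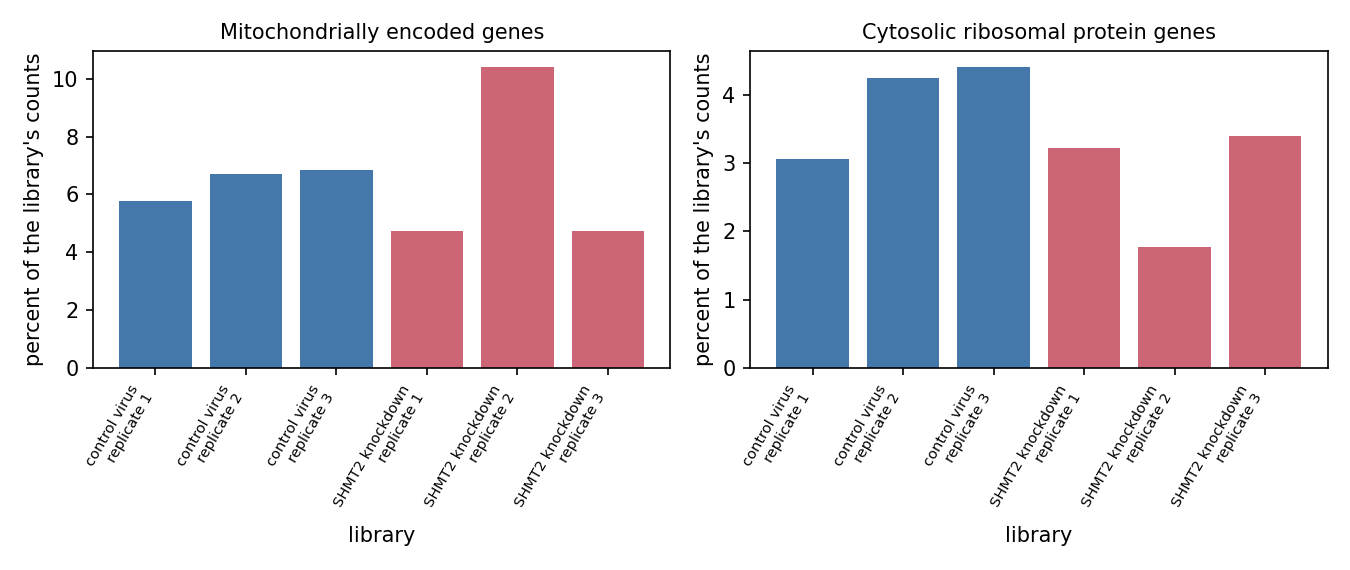
Percent of each library's counts in mitochondrially encoded genes (left) and in cytosolic ribosomal protein genes (right), one bar per library, control virus in blue and SHMT2 knockdown in red. Knockdown replicate 2 has the highest mitochondrial share (10.42%) and the lowest ribosomal protein share (1.77%).

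Of the 39 gene lists with at least 5 tested genes, camera with a preset correlation of 0.01 called 6 higher and 5 lower. With a correlation estimated per list, camera called 0 lists, 5 had an unadjusted p below 0.05, and the lowest adjusted p was 0.194. By fry, which asks whether a list's genes move one way on balance, 28 lists passed. Interferon-stimulated genes showed the widest shift, with 18 of 25 tested members higher and 0 lower in edgeR (18 and 0 adjusted over the list alone), a median log2 fold change of 1.85 and an adjusted p of 1.92e-05 (adjusted p = 0.194 with an estimated correlation). The list holds 40 genes, and those left out of the test had too few counts, so the 25 do not describe the whole list. Of those left out, IFI44L had 0 counts in both groups and IFI27 had 34 in each. MX1 had 0 control and 39 knockdown counts. IFIT1, which binds viral RNA, rose from 3.65 ± 0.218 to 23.7 ± 1.19 CPM, IFITM3, which blocks viral entry, from 18.9 ± 1.93 to 100 ± 7.53 CPM, and the RNA sensor IFIH1 from 0.837 ± 0.177 to 10.4 ± 0.195 CPM (SD, n = 3).

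NF-kB and inflammatory genes were higher in 13 and lower in 3 of 19 tested members (13 and 3 adjusted over the list alone; median 1.07, adjusted p = 0.00436, and adjusted p = 0.311 with an estimated correlation). The chemokine CCL2 rose from 3.55 ± 0.458 to 59.5 ± 2.35 CPM and TNFAIP2 from 22.2 ± 0.861 to 189 ± 12.7 CPM, while the cytokine LIF fell from 119 ± 5.31 to 60.2 ± 2.67 CPM. Antigen presentation genes were higher in 7 of 13 tested members and lower in 0 (8 and 0 adjusted over the list alone; median 0.49, adjusted p = 0.0137, and adjusted p = 0.567 with an estimated correlation). The immunoproteasome subunits PSMB8 and PSMB9 changed by 4.92 (SE 0.45) and 2.83 (SE 0.41). This list's call was lost without control replicate 1 (adjusted p = 0.0818), and its median was 0.77 after a correction for gene length and GC content.

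ATF4 amino acid response genes were higher in 22 and lower in 3 of 36 tested members (23 and 3 adjusted over the list alone; median 0.49, adjusted p = 0.000978, and adjusted p = 0.382 with an estimated correlation). The stress cytokine GDF15 rose from 55.7 ± 1.52 to 168 ± 13.8 CPM, the cystine transporter SLC7A11 from 36.8 ± 5.46 to 105 ± 9.02 CPM and the transsulfuration enzyme CTH from 3.36 ± 0.276 to 11.6 ± 0.52 CPM. EIF4EBP1, a translation repressor on the same list, fell by 1.28 on the log2 scale. Hypoxia-induced genes were higher in 14 and lower in 4 of 23 (15 and 4 adjusted over the list alone; median 0.53, adjusted p = 0.0257, and adjusted p = 0.311 with an estimated correlation). BNIP3, a mitophagy receptor, rose from 79.7 ± 9.53 to 190 ± 18.6 CPM, whereas ANGPTL4 fell from 163 ± 9.64 to 67.8 ± 13.2 CPM.

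DNA replication and S phase genes were lower in 24 and higher in 0 of 40 tested members in edgeR (25 and 0 adjusted over the list alone; median -0.35, adjusted p = 2.85e-05, and adjusted p = 0.311 with an estimated correlation). UHRF1, which maintains DNA methylation at replication, fell from 213 ± 4.08 to 93.9 ± 2.52 CPM, and the helicase subunit MCM5 from 144 ± 1.96 to 68.2 ± 3.11 CPM. CDC25A fell by 1.40 on the log2 scale and lies in a window of neighbouring genes with a median of -0.49. G2 and mitosis genes were higher in 18 and lower in 4 of 36 (19 and 4 adjusted over the list alone; median 0.51, adjusted p = 0.00436, and adjusted p = 0.558 with an estimated correlation). CDK1 rose from 141 ± 19.5 to 294 ± 28.7 CPM and the kinetochore motor CENPE from 7.66 ± 3.14 to 73.2 ± 27.8 CPM. Of 26 tested p53 and arrest genes, 6 rose and 9 fell (6 and 9 adjusted over the list alone), with no call for the list (adjusted p = 0.579). The cell cycle inhibitor CDKN1A fell from 107 ± 9.06 to 33.0 ± 1.07 CPM.

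Of 78 cytosolic ribosomal protein genes, 34 fell and 0 rose in edgeR (31 and 0 adjusted over the list alone; median -0.58, adjusted p = 2.05e-05, and adjusted p = 0.684 with an estimated correlation). RPL4 fell from 2120 ± 231 to 1230 ± 111 CPM, and the ribosomal protein share was lowest in knockdown replicate 2 (1.77%), while that of control replicate 1 (3.06%) lay below those of knockdown replicates 1 and 3. The list did not pass fry (adjusted p = 0.117). The count of lower members was 22 without control replicate 2, 21 without control replicate 3 and 67 without control replicate 1 and knockdown replicate 2 together, and the list stayed called in each case. Of 82 mitochondrial ribosome and translation genes, 35 fell and 3 rose (35 and 2 adjusted over the list alone; median -0.47, adjusted p = 5.17e-05, and adjusted p = 0.567 with an estimated correlation). Without control replicate 1 and knockdown replicate 2 together, 56 of them were lower. MRPS7 fell from 119 ± 9.26 to 56.9 ± 3.74 CPM and MRPS18B from 123 ± 8.21 to 63.4 ± 4.73 CPM. Of 17 mitochondrial unfolded protein response genes, 11 fell and 1 rose (11 and 1 adjusted over the list alone; median -0.56, adjusted p = 0.0297, and adjusted p = 0.567 with an estimated correlation). PHB2 changed by -1.07 and the mitochondrial chaperone TRAP1 by -0.81. This call was lost when control replicate 1 and knockdown replicate 2 were both left out (adjusted p = 0.0765), where the median was -0.54 with 11 members lower and 5 higher. With all libraries, the list's median was -0.30 after a correction for gene length and GC content and -0.29 after subtraction of each gene's window median.

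The 13 mitochondrially encoded respiratory chain genes gave 0 calls in edgeR (0 adjusted over the list alone) and a median of -0.06 with all libraries. Without knockdown replicate 2, the library with 10.42% mitochondrial counts, 10 of the 13 were lower, the median was -0.55 and the list was called (adjusted p = 0.00544). MT-CO1 stood at 13900 ± 1070 and 13000 ± 6100 CPM and MT-ND4 at 10200 ± 732 and 13300 ± 8620 CPM in control and knockdown libraries (SD, n = 3). Nuclear-encoded subunits of complex I were higher in 3 and lower in 7 of 36 (1 and 2 adjusted over the list alone; adjusted p = 0.21), and those of complexes II to V were higher in 0 and lower in 12 of 37 in edgeR (0 and 7 adjusted over the list alone; adjusted p = 0.0631). The latter list was called without control replicate 1 or knockdown replicate 1 or 3 (adjusted p from 0.00629 to 0.0273), without control replicate 1 and knockdown replicate 2 together (0.0171) and with no filter on low counts (0.0296). UQCRC1, a complex III core subunit, fell from 210 ± 30.1 to 112 ± 19.5 CPM and lies in a window of neighbouring genes with a median of -0.49.

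Of 24 tested genes of cholesterol synthesis and uptake, 17 fell and 0 rose in edgeR (19 and 0 adjusted over the list alone; median -0.68, adjusted p = 5.17e-05, and adjusted p = 0.311 with an estimated correlation). The transcription factor SREBF2 fell from 107 ± 2.86 to 48.3 ± 1.66 CPM and squalene epoxidase SQLE from 182 ± 7.95 to 96.6 ± 5.16 CPM. Fatty acid genes were not called as a list (2 higher and 7 lower of 21, 2 and 7 adjusted over the list alone; adjusted p = 0.366), although FASN, the fatty acid synthase, fell from 295 ± 21.6 to 117 ± 9.49 CPM.

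**Figure D3:**
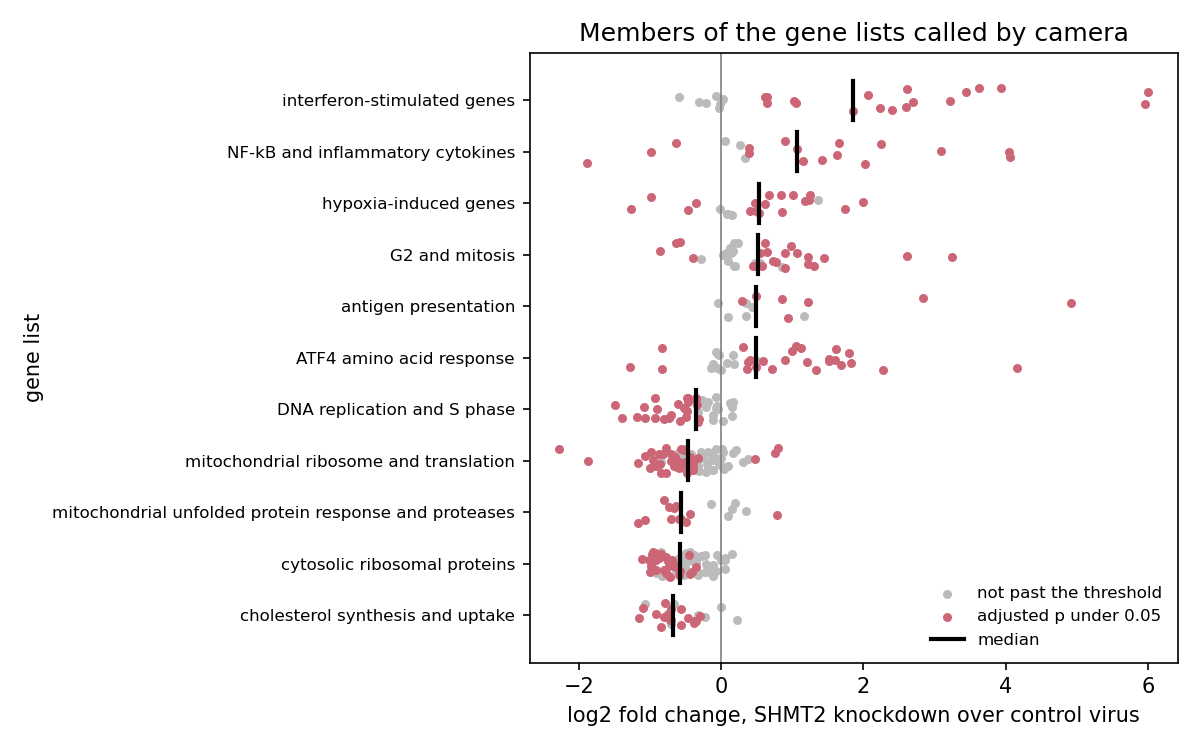
Log2 fold change (SHMT2 knockdown over control virus) of each tested member of the 11 gene lists called by camera, one point per gene, red where the adjusted p was below 0.05 and grey otherwise. Black bars are list medians, from 1.85 for interferon-stimulated genes to -0.68 for cholesterol synthesis and uptake.

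Several lists held changes in both directions and were not called. Epithelial markers were higher in 11 and lower in 4 of 19 (11 and 4 adjusted over the list alone; adjusted p = 0.0631), and were called without control replicate 3 or knockdown replicate 1 or 2 (adjusted p from 0.0341 to 0.0484) and with no filter on low counts (0.0318). CLDN1 rose from 9.17 ± 0.998 to 73.5 ± 12.8 CPM while EPCAM fell from 18.1 ± 0.527 to 6.95 ± 0.863 CPM. Of 28 collagen and matrix genes, 13 rose and 10 fell (13 and 10 adjusted over the list alone; adjusted p = 0.245). The basement membrane collagens COL4A1 and COL4A2 rose to 18.0 ± 1.34 and 24.0 ± 3.20 CPM from 0.556 ± 0.0818 and 0.73 ± 0.139 CPM. Mesenchymal genes were higher in 8 and lower in 6 of 21 (10 and 6 adjusted over the list alone; adjusted p = 0.712), and the gelatinase MMP2 fell from 133 ± 2.93 to 21.4 ± 3.07 CPM. TGF-beta response genes were higher in 7 and lower in 11 of 23 (7 and 12 adjusted over the list alone; adjusted p = 0.145), and ID3, an inhibitor of helix-loop-helix factors, fell from 114 ± 12.2 to 12.1 ± 1.78 CPM. Purine synthesis genes were higher in 2 and lower in 7 of 15 (3 and 8 adjusted over the list alone; adjusted p = 0.145), with PFAS falling from 149 ± 8.42 to 68.3 ± 6.17 CPM.

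Markers of other cell types were mostly too low to test. Of the immune, fibroblast, endothelial, acinar, endocrine and embryonic kidney marker lists, 2, 4, 3, 0, 4 and 4 genes were tested, 1, 1, 1, 0, 1 and 1 of them rose, and 1, 2, 1, 0, 0 and 1 fell (the same numbers adjusted over the list alone). The members that rose were CD14, COL3A1, KDR, SCG2 and LHX1. KDR rose from 0.257 ± 0.00855 to 6.20 ± 0.591 CPM, and CD14, at 1.19 ± 0.425 and 2.37 ± 0.673 CPM, lost its call without control replicate 1 or 2 or knockdown replicate 1 or 3 (adjusted p from 0.0783 to 0.122).

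Changes were not spread evenly over the genome, a summary chosen after the gene results were seen. When tested genes were ordered by position and divided into 234 windows of at least 50 genes, and log2 fold changes were corrected for gene length and GC content, 8 windows had a median beyond the largest of 1000 shuffles (0.46). On chromosome X, the window from 120426148 to 150765108 (LAMP2 to MTMR1) had a median of 1.30, and 90% of its genes were higher before correction. On chromosome 8, the window from 22367278 to 30727846 (SLC39A14 to GSR) had a median of -1.03, and 92% of its genes were lower. Named genes in these windows were LAMP2, XIAP and HPRT1 on chromosome X and SCARA3, TNFRSF10A, SLC39A14 and GSR on chromosome 8. The 8 windows held 288 of the 6369 called genes that lay in windows. Some windows short of the 0.46 limit were also shifted in every knockdown library, so 288 does not bound the calls in shifted regions. On chromosome 3, those from 3126933 to 14143680 and from 51662693 to 58172251 had medians of -0.44 and -0.42. On chromosome 1, that from 183620846 to 203078740 had a median of 0.44. On chromosome 11, that from 9573670 to 27363234 had a median of 0.45. On chromosome 17, that from 80415165 to 83095122 had a median of -0.46, short of the limit only before rounding. Before correction, 94.6% of the genes in this chromosome 17 window were lower. The corrected window medians had an SD of 0.22.

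**Figure D4:**
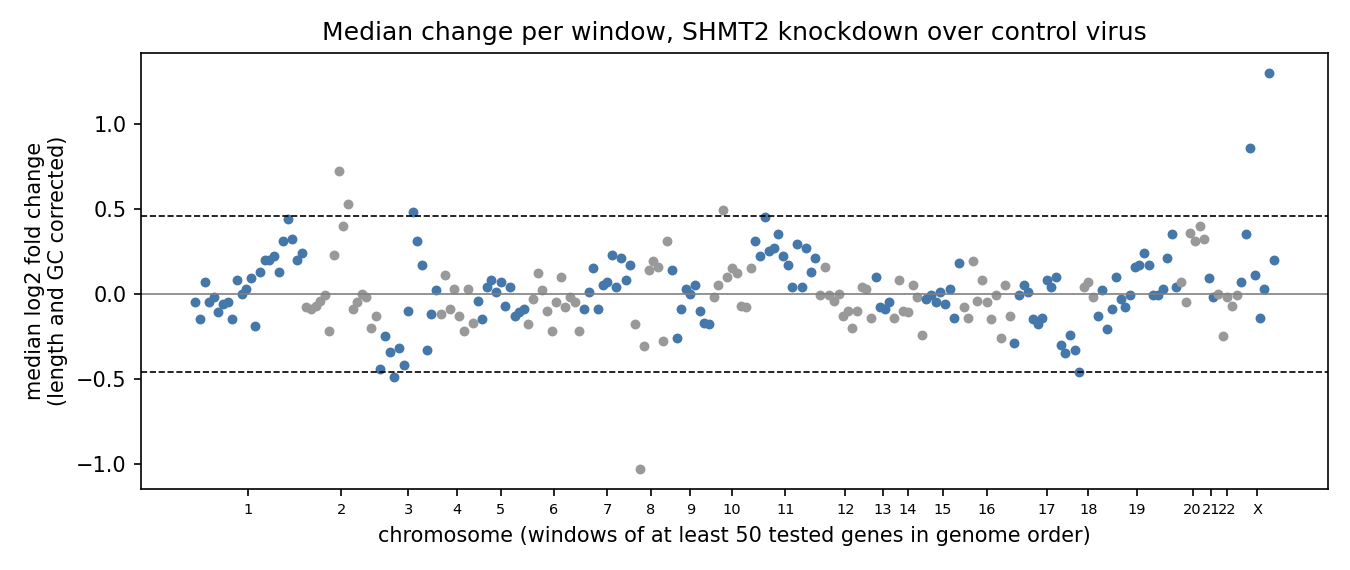
Median log2 fold change (SHMT2 knockdown over control virus, corrected for gene length and GC content) in 234 windows of neighbouring tested genes along chromosomes 1 to 22 and X, one point per window, with colours alternating by chromosome. Dashed lines mark the largest median of 1000 shuffles (0.46 in either direction), and 8 windows lie beyond them, from 1.30 on chromosome X to -1.03 on chromosome 8.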

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

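Leaving out both control replicate 1 and knockdown replicate 2 was chosen after the data were seen, and the other alternatives were fixed before. SHMT2 was lower and past the threshold under every alternative tried, with a log2 fold change from -5.07 (without knockdown replicate 1) to -4.60 (without knockdown replicate 2) on leaving out single libraries and -3.89 by limma on log2(FPKM + 1). The count of changed genes ranged from 4748 to 6784 when single libraries were left out (2440 to 3504 higher, 2308 to 3465 lower), and 4674 of the 6372 calls kept their direction and call in the lowest of these, without control replicate 2. DESeq2 called 6513 genes and limma-voom 6425. Without both libraries that stood apart, 9135 genes were called and 6318 of the 6372 kept, but the 4 libraries left are pairs of unusually close ones. In none of these alternatives was a called gene called in the opposite direction. Scaling by library size alone moved the median of all genes to 0.086 and the share of higher calls from 51.5% to 60.2%. Counts fell by construction at stricter thresholds, to 4166 (2143 higher, 2023 lower) at an adjusted p of 0.01, 1917 (1206 and 711) at 2-fold or more and 2017 (1192 and 825) by glmTreat against 1.5-fold.

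Of the gene lists, 11 were called with the preset correlation and 11 to 15 when single libraries were left out. With an estimated correlation camera called 0, with 5 at an unadjusted p below 0.05, and fry, which makes no comparison with other genes, called 28. Fisher's test called 18 combinations of list and direction, and 18 to 25 when single libraries were left out. These include shortfalls, where fewer members were called in a direction than among other genes. The smallest adjusted p in Fisher's test, 3.86e-09, was such a case, with 0 of 78 cytosolic ribosomal protein genes higher. MT-ND4 reversed from 0.39, not called, to -0.30 without knockdown replicate 2 (up to 0.64 without another single library, knockdown replicate 1) and to -0.34 without both libraries that stood apart. That knockdown library alone holds 10.42% mitochondrial counts.

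The labels give both groups the replicate numbers 1 to 3. With the replicate number as a block, 5444 genes were called (2834 higher, 2610 lower), 5413 of them among the 6372 and in the same direction, and the SHMT2 log2 fold change was -4.84. Deviations from the group means correlated at -0.30, -0.28 and 0.30 across genes for numbers 1, 2 and 3. Control replicate 1 correlated best with knockdown replicate 2 (0.45). These are the libraries that stood apart in their groups of 3, and they dominate such deviations. The values therefore cannot decide whether a shared number marks a shared culture or day. With the block, the calls of SHMT1 (adjusted p = 0.1), MTHFD2 (0.0786), NDUFS1 (0.0653) and LAPTM5 (0.0606) were lost, and the lists of complexes II to V and of epithelial markers were called (0.0436 each). No other named gene or list changed its call. In the simulation, with 199 changed genes tested, 22% of 1.5-fold changes were recovered. The adjustment is less strict where more genes change, so that share is not the one of the real comparison.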

Other observations

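The tests for both outlying libraries, for other cell types and for chance splits of the libraries were chosen only after the results they bear on were seen. Of 309 pathways in the table's own KEGG annotation, 2 were called by camera with the preset correlation and 0 with an estimated one, where the adjusted p was 0.984 for both. The ribosome pathway was lower (52 of 126 genes lower, 2 higher, median -0.52). The herpes simplex infection pathway was higher (178 of 400 genes higher, 47 lower, median 0.38), a set in which 262 of the 400 genes are zinc finger genes named ZNF. Of 423 tested genes named ZNF with a number, 190 rose and 48 fell, with a median of 0.41 that became 0.26 after the length and GC correction. Some genes were nearly silent in one group. With at most 3 counts over the 3 control libraries and at least 1 CPM in each knockdown library there were 22 genes, among them the arginine transporter SLC7A2 (2 against 431 counts), the transcription factor FLI1 (2 against 401) and the surface antigen CEACAM6 (1 against 323). The reverse held for 6 genes, BRINP3, EPHA3, FSTL5, NCAM2, PRR16 and RAB44. CDKN2A and CDKN2B on chromosome 9 had 0 counts in all 6 libraries. On one side of them, MTAP had 20 counts over the control and 8 over the knockdown libraries. DMRTA1, on the other side, had 245 counts over the control and 207 over the knockdown libraries.

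The real grouping gave 6372 called genes. Of the 10 ways to split the 6 libraries into 3 and 3, 1 gave as many, the real one, and the highest of the others gave 0 in edgeR, with 7 to 356 genes at an unadjusted p below 0.05. With 10 splits, a share below 0.05 cannot be reached. Every other split mixes control and knockdown libraries, which adds the difference between the groups to the spread. Low counts there follow from this, so the contrast with 6372 decides nothing.

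The lists of cytosolic ribosomal protein and mitochondrial ribosome genes were called lower in the knockdown libraries, with medians of -0.58 and -0.47 and 34 of 78 and 35 of 82 members called lower. Without control replicate 1 and knockdown replicate 2 the medians were -0.53 and -0.38, which argues against these libraries as the whole cause. After the length and GC correction they were -0.53 and -0.32, and after subtracting the median of each gene's own window -0.56 and -0.40, which argues against those trends as the whole cause. A coordinated fall of translation genes in the cells that received the knockdown virus stays open as a hypothesis, but neither list was called with an estimated correlation (adjusted p = 0.684 and 0.567), and the ribosomal protein list did not pass fry (adjusted p = 0.117).

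The 25 tested interferon-stimulated genes were higher by a median of 1.85. Without both libraries that stood apart the median was 2.03 with 19 members called higher, and after window subtraction it was 1.61, which argues against both as the whole cause. The first test of another cell type, on the marker lists, decided nothing, since only 17 markers were tested and at most 1 on any list rose. A second test was then set up with the counts already known, limits included, so its outcome was fixed. In it, 12 abundant immune, stromal, endothelial and acinar markers, LYZ, PTPRC, TYROBP, COL1A2, DCN, LUM, PECAM1, CDH5, VWF, PRSS1, CPA1 and PNLIP, summed to 17 counts over the 3 knockdown libraries. Those transcripts were nearly absent, but KDR, COL3A1 and CD14 of the same marker lists rose and were not among the 12. The sum therefore decides nothing about those cells. Several explanations stay open, among them other cell types, another cultured line and a difference between the cell populations that received the viruses. A response to the virus itself that differed between the preparations and a response to loss of SHMT2 also stay open. The first test touched other cell types and an embryonic kidney line without deciding, and the others were not tested.

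Runs of neighbouring genes shifted together, and 8 windows still lay beyond the largest shuffle (0.46) after the length and GC correction, which argues against that trend. In 10 windows chosen on odd-numbered genes, 81.2% of the 250 even-numbered genes moved in the window's direction, against 57.1% over all windows. The share was 80% to 96% in 7 of the windows, where a few strongly regulated genes do not account for the run, but 72%, 64% and 64% in the other 3, where that stays open. All 3 knockdown libraries were shifted beyond 0.2 in 8 of those 10 windows, but the least shift in one of the 8 was 0.2004, at the limit. In the 7 others of these 8, every knockdown library was shifted by more than 0.25, which argues against one outlying knockdown library for those windows. All were measured against the same control mean, so this cannot exclude an outlying control library. Against the other controls, control replicates 1, 2 and 3 lay at -0.01, 0.01 and 0 in the chromosome X window from LAMP2 to MTMR1. In the chromosome 8 window from SLC39A14 to GSR they lay at 0.01, 0 and -0.02, which argues against an outlying control in these windows. A candidate explanation is a difference in copy number between the cell populations that received the viruses, for which the pooled share of 81.2% passed the bound set beforehand, carried by the 7 windows with a share of 80% to 96%, while the bound of 8 windows was met only with the window at the limit. Shared regulation of whole regions predicts the same values and stays open, no DNA was analysed here, and any such difference could make part of the 6372 calls independent of SHMT2.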
